A study of Homo sapiens with 6 samples.

How the data were processed

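Gene expression was measured in 6 samples of CAL-27, an established cell line from a squamous cell carcinoma of the tongue, on 6 Affymetrix arrays hybridised with biotin-labelled cRNA. Per the labels, 3 samples were infected with a control lentivirus (shCtrl) and 3 with a lentivirus whose short hairpin RNA targets SCUBE3 (shSCUBE3). Groups and replicate numbers were taken from the sample titles. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. No batch or date is given with the samples.

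The authors deposited a table of log2 expression values with 1 column per array, made with RMA per the submitters' processing notes. RMA corrects the background of each array, normalizes the arrays to a common distribution and summarises the probes of each probe set. The version, the software, the array library and any filter are not given in the sources used here. The log2 scale was read from the values themselves, which lay between 0.44 and 14.1. The labels name the PrimeView design, whereas the identifiers in the deposited table are transcript clusters and control names of a later Affymetrix whole-transcript design, so the array type stated in the labels is uncertain. No genome build was given, and no coordinates are reported.

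The table holds 27189 identifiers, of which 21448 are transcript clusters, 2555 are bare numbers and the others are controls. The platform annotation gave 1 gene symbol for 17709 probe sets and several symbols for 0. The remaining 3739 transcript clusters had no name in the annotation used here. All 17709 matched the reference gene table by gene number, with 0 symbols differing. For the 20 genes with more than 1 probe set, the probe set with the highest mean over the 6 arrays was kept, which left 17687 genes.

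Genes were tested on the log2 values with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with the group as the only term, 2-sided, and Benjamini-Hochberg adjustment over all 17687 genes. A gene counted as past the threshold with an adjusted p under 0.05 and a fold change of at least 1.3 in either direction, the limits given in the series' design text. That text names Welch's test, which was run on the same values as an alternative and is called the methods' t-test. Fold changes are shSCUBE3 minus shCtrl on the log2 scale with limma's standard error. This design, 33 gene lists, the alternatives and the rule for naming genes were chosen before the data were examined, except where stated.

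Each list with at least 5 measured genes was tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over the 33 lists. Camera asks whether a list shifts against all other genes. An estimated correlation and fry were the alternatives; fry asks whether the genes of a list move, on balance, in 1 direction and compares them with no other genes. The lists cover TGF-beta, BMP, Hedgehog, FGF, EGFR, ERK, Wnt, Notch, YAP/TAZ and PI3K signalling, epithelial, mesenchymal, squamous and basal genes, proteases, cell cycle, p53, apoptosis, hypoxia, stress responses, lipid synthesis, interferon, inflammation, NRF2, angiogenesis, ribosomal and respiratory genes, housekeeping genes, and markers of fibroblasts, leukocytes and endothelium. List members without a named probe set were not analysed here. The rule for named genes took the SCUBE family, the 10 largest increases and the 10 largest decreases past the threshold with no overlap between the groups, and up to 4 members of each list past its test or up to 2 of any other list. Where the largest difference of a list is given among members above background, these were above it on at least 1 array of each group, a choice made after the results were seen. Where no member was past the threshold, the member with the largest change was taken. PDIA4, HERPUD1, XBP1, EDEM1, KRT14, DSG3, CXCL8, MYC, ADAM17, EGFR, VIM, FN1, ITGA5 and KLF4 are named outside this rule and were chosen after their values were seen.

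Background was set after the data were seen, as the 95th percentile of the 612 antigenomic negative-control probe sets of each array, and lay between 4.36 and 4.58. Where a gene was not above it on any array of a group, the change is given as a bound: the mean of the brighter group against the mean over the arrays of the other group of the higher of background and the gene's own value. Arrays have no read depth, and their number limits the precision. The procedure was tested on simulated data with the spread of these 6 arrays, 17687 genes and 200.0 changed genes in 20.0 draws. For shSCUBE3 against shCtrl limma recovered 15.4% of simulated changes of 0.5 log2, 67.3% of changes of 1 and 88.6% of changes of 1.5, and 4.49% of its calls were false. Welch's test recovered 12.6% of changes of 1.5. Simulated genes varied independently of each other, with no difference between arrays as a whole. They held fewer changed genes than the 874 called here, so the recovered and false shares need not hold for these data.

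The alternatives were the methods' t-test, an intensity trend with a robust prior, array weights, a filter on the dimmest 30% of genes, the mean of a gene's probe sets, a test of every transcript cluster, quantile normalization or median centring of the deposited values, other thresholds, the replicate number as a block, and each array left out in turn. Cyclic loess and a restriction to genes above background were added after the data were seen. Control probe sets were left out of the gene tests and examined separately. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.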

Results

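The data comprise 6 arrays of CAL-27 tongue carcinoma cells, 3 from cells with a control hairpin (shCtrl) and 3 from cells with a hairpin against SCUBE3 (shSCUBE3). SCUBE3 encodes a secreted and cell-surface glycoprotein with EGF-like repeats and a CUB domain. Each array gave log2 RMA values for 17687 named genes, with medians between 5.62 and 5.64. Between 72.9% and 76.9% of the genes lay above the background of the array. Pearson correlations across genes, which are not independent replicates, were 0.984 to 0.986 within groups and 0.976 to 0.978 between groups. The first principal component held 39.9% of the variance and separated the groups.

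The comparison asks which transcripts differ between cells with the hairpin against SCUBE3 and cells with the control hairpin. With 1 hairpin group against SCUBE3, no result below can tell an effect of lower SCUBE3 from another response to the hairpin or vector. The targeted gene was read at background. The SCUBE3 probe set gave 3.77 ± 0.28 in shCtrl and 3.66 ± 0.45 in shSCUBE3 (mean ± SD, n = 3), a log2 fold change of -0.11 ± 0.23 (SE, 95% interval -0.65 to 0.43, adjusted p = 0.839). It was above background on 0 of the 6 arrays, so that no fold is read from it and it does not check the labels. Its sign turned without shCtrl 1 (0.019) and without shSCUBE3 2 (0.063). SCUBE1, a related gene above background on all arrays, had a log2 fold change of 0.34 ± 0.15 (adjusted p = 0.255). SCUBE2 was also at background, so that no fold is read from it either, with a difference of 0.050 ± 0.17 (adjusted p = 0.907) that turned to -0.097 without shCtrl 2 and to -0.049 without shSCUBE3 3.

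Cells with the hairpin against SCUBE3 had higher levels of type I interferon-stimulated genes and of a joint list of ATF4 targets and unfolded protein response genes. They had lower levels of cholesterol synthesis genes, of YAP/TAZ targets, of basal keratinocyte and hemidesmosome genes and of cell cycle genes. Of these lists only the interferon genes also shifted with an estimated correlation between genes. The others had adjusted p between 0.0568 and 0.195 with an estimated correlation. For the cholesterol, basal and DNA replication lists the estimate was -0.012, -0.042 and 0.0061, below the preset 0.01. Their loss therefore does not come from a higher correlation within these lists. In all, 874 genes (4.94% of those tested) passed the threshold, 337 higher and 537 lower in shSCUBE3, with a median absolute log2 fold change of 0.64. Of these, 92 changed at least 2-fold, 34 upward and 58 downward. The groups did not overlap for any of the 874 genes, which the threshold itself nearly ensures with 3 arrays against 3. Over all genes 26.2% were without overlap where chance gives 10.0%, but genes are not independent of each other. The count was 245 without shCtrl 1, 325 without shCtrl 2, 306 without shCtrl 3, 415 without shSCUBE3 1, 353 without shSCUBE3 2 and 307 without shSCUBE3 3, and 206 genes passed in all 6 of these fits. The methods' t-test with Benjamini-Hochberg adjustment passed 39 genes at the same limits. With limma 3517 of all 17687 genes had an unadjusted p under 0.05, and such counts within a list are to be read against that share.

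The largest increases were in RSAD2, the antiviral enzyme viperin, and CCL20, a chemokine that attracts CCR6-bearing leukocytes. RSAD2 rose from 6.10 ± 0.19 to 7.89 ± 0.23 (mean ± SD, n = 3), a log2 fold change of 1.79 ± 0.15 (SE, adjusted p = 0.0021). CCL20 rose by 1.72 ± 0.11 (adjusted p = 0.00152). TMEM45A rose by 1.65 ± 0.14 and was above background on 1 of the 3 shCtrl arrays. Its shCtrl mean of 4.45 lay within the range of the background, so the size of its rise is uncertain. SLC7A11, the cystine importer of system xc-, rose by 1.56 ± 0.13, and ASNS, asparagine synthetase, by 1.52 ± 0.11. IFI44L and DDX60, both interferon-stimulated, rose by 1.53 ± 0.16 and 1.47 ± 0.11. ABCA12, a lipid transporter of keratinocytes, rose by 1.36 ± 0.16. ARL14EPL and CEP15 were not above background in shCtrl and were at least 2.06-fold and at least 1.68-fold higher in shSCUBE3 (adjusted p = 0.00209 and 0.00447).

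The largest decrease was in SEC23A, a subunit of the COPII coat of vesicles leaving the endoplasmic reticulum. SEC23A fell from 7.13 ± 0.13 to 5.46 ± 0.017 (mean ± SD, n = 3), a log2 fold change of -1.66 ± 0.11 (SE, adjusted p = 0.00152). MACC1, a regulator of MET expression, had a log2 fold change of -1.63 ± 0.11. PPP3R1, the regulatory subunit of calcineurin, and RGS10, a regulator of G protein signalling, both had -1.61, with SEs of 0.18 and 0.13. COXFA4, formerly NDUFA4 and a subunit of cytochrome c oxidase, and SMC1A, a core subunit of cohesin, both had -1.52, with SEs of 0.12 and 0.14. UGCG, which makes glucosylceramide, had -1.49 ± 0.098, SCD, the stearoyl-CoA desaturase, -1.47 ± 0.095, and WSB2 -1.45 ± 0.16. ANKRD1, a YAP/TAZ target, was not above background in shSCUBE3 and was at least 2.13-fold lower there (adjusted p = 0.00498). The 10 largest increases and the 10 largest decreases passed the threshold in each of the 6 fits without 1 array.

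**Figure D1:**
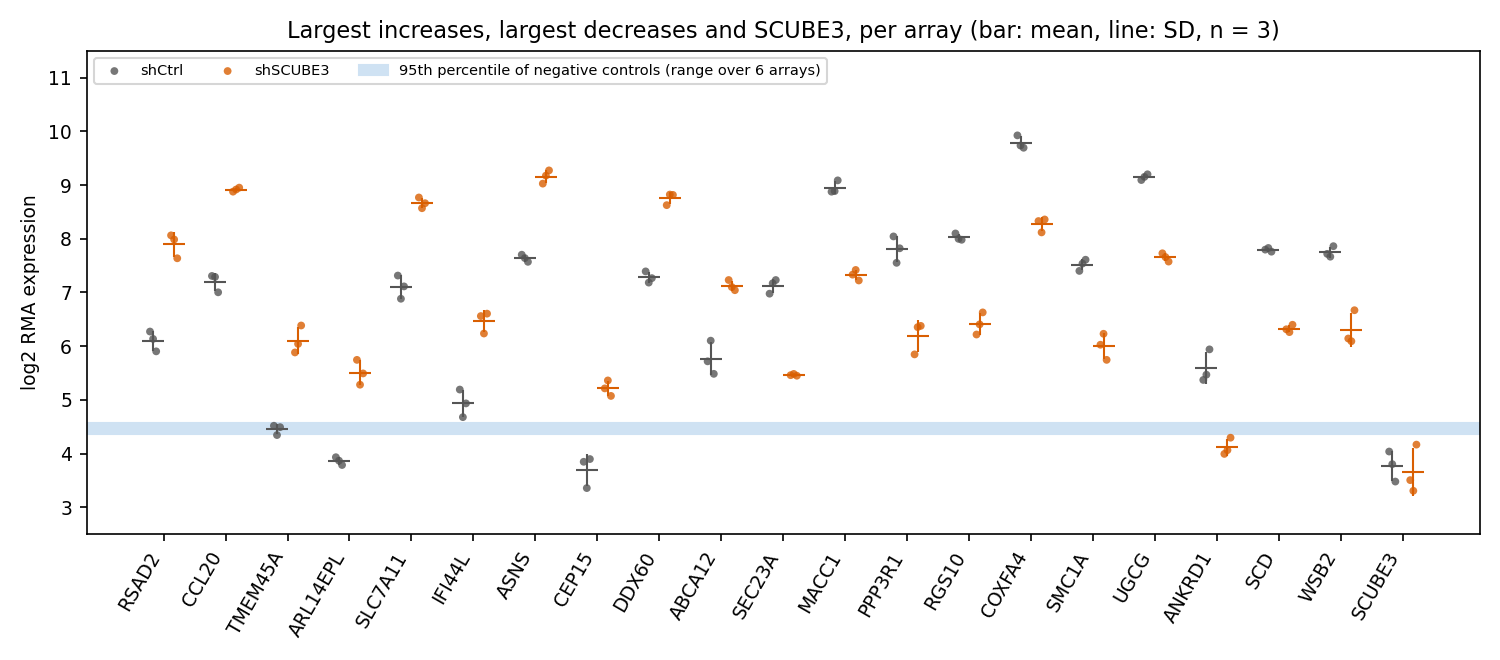
Log2 RMA expression (vertical axis) of the 10 largest increases, the 10 largest decreases and SCUBE3 on each array, with points for arrays, horizontal bars for group means and vertical lines for the SD (n = 3 per group). The shaded band is the range of the background over the 6 arrays, 4.36 to 4.58. The 20 changed genes were chosen to have no overlap between groups, and SCUBE3 lies below the band on all 6 arrays.

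Among the 33 gene lists, 11 shifted against all other genes, 3 upward and 8 downward. With an estimated correlation 1 list passed, the type I interferon-stimulated genes. Of its 37 measured members 14 rose, 0 fell and 23 did not pass, and 16 rose when adjusted over the list alone (camera adjusted p = 1.49e-17; adjusted p = 0.0318 with an estimated correlation). In direction 36 of the 37 were higher in shSCUBE3, with a median log2 fold change of 0.35. Besides RSAD2, IFI44L and DDX60, RIGI, the cytosolic sensor of viral RNA, rose by 1.20 ± 0.11 (SE, adjusted p = 0.00227). Between 10 and 13 members rose in the fits without 1 array.

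The ATF4 and unfolded protein response list shifted upward: 12 of 37 members rose and 1 fell, or 17 and 2 when adjusted over the list alone (adjusted p = 4.49e-06; adjusted p = 0.195 with an estimated correlation). The largest rises, besides SLC7A11 and ASNS, were in PSAT1 of serine synthesis, by 1.20 ± 0.10, and MTHFD2 of mitochondrial folate metabolism, by 0.79 ± 0.099. The member that fell, PDIA4, a disulfide isomerase of the endoplasmic reticulum, had a log2 fold change of -0.48, with the call lost in all 6 fits without 1 array. The list joins ATF4 targets with unfolded protein response genes, and these parts were not tested apart. From the latter part HERPUD1 and XBP1 rose by 0.52 and 0.58, with calls kept in 0 and 1 of the 6 fits. EDEM1, of the same part, was past the threshold and lower without the dimmest 30% of genes (-0.50, adjusted p = 0.0177). Between 4 and 6 members rose in the fits without 1 array. Of 24 NRF2 targets 4 rose and 0 fell, or 6 and 0 when adjusted over the list alone (adjusted p = 0.0063; adjusted p = 0.277 with an estimated correlation). They were SLC7A11, NQO1, the quinone reductase, by 0.80 ± 0.097, ME1, malic enzyme, by 0.62 ± 0.11, and ABCC2, an export pump whose probe set was at background in both groups. SLC7A11 also belongs to the ATF4 list and ME1 to the fatty acid list. ME1 kept its call in 1 of the 6 fits without 1 array and ABCC2 in 0.

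Cholesterol synthesis genes shifted downward: 6 of 20 fell and 0 rose, or 11 and 0 when adjusted over the list alone (adjusted p = 2.19e-07; adjusted p = 0.0568 with an estimated correlation). DHCR7, the last enzyme of the pathway to cholesterol through 7-dehydrocholesterol, had a log2 fold change of -1.02 ± 0.12 (SE, adjusted p = 0.00518). MSMO1, the sterol C4 methyl oxidase, had -0.78 ± 0.10, HMGCS1, the cytosolic HMG-CoA synthase, -0.74 ± 0.11, and STARD4, a sterol carrier, -0.67 ± 0.14. HMGCS1 lost its call without shCtrl 1 (adjusted p = 0.0502), and STARD4 in all 6 fits without 1 array. Between 2 and 4 members fell in those fits. Of 16 fatty acid synthesis genes 3 fell and 2 rose, or 5 and 2 when adjusted over the list alone, with 1 to 2 lower and 0 to 1 higher in the fits without 1 array (adjusted p = 0.00516; adjusted p = 0.147 with an estimated correlation). SCD and FASN, the fatty acid synthase, fell, FASN by 0.77 ± 0.12 with the call lost without shCtrl 1 or shCtrl 3. ME1, which supplies NADPH, and ACSL5, which activates fatty acids, were the members that rose, ACSL5 by 0.64 ± 0.12 with the call lost in all 6 fits without 1 array.

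YAP/TAZ targets shifted downward: 7 of 20 fell and 0 rose, or 8 and 0 when adjusted over the list alone (adjusted p = 3.33e-07; adjusted p = 0.0583 with an estimated correlation). Besides ANKRD1, CRIM1, a transmembrane BMP-binding protein, had a log2 fold change of -1.05 ± 0.11. F3, tissue factor, had -1.02 ± 0.091, and PTPN14, a phosphatase that binds YAP, -0.82 ± 0.11. Between 5 and 6 members fell in the fits without 1 array, these 4 in all of them.

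Basal keratinocyte and hemidesmosome genes shifted downward: 5 of 13 fell and 1 rose, or 7 and 1 when adjusted over the list alone (adjusted p = 3.11e-05; adjusted p = 0.0583 with an estimated correlation). The integrin subunits ITGA2 and ITGA3 had log2 fold changes of -1.25 ± 0.16 and -1.14 ± 0.13. The basal keratin KRT5 had -1.05 ± 0.10 and the hyaluronan receptor CD44 -0.88 ± 0.092. KRT14, the usual partner of KRT5, was the member that rose, by 0.51, with the call lost in all 6 fits without 1 array. Between 4 and 5 members fell in the fits without 1 array, ITGA2, ITGA3, KRT5 and CD44 in all of them.

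Epithelial junction genes also shifted downward: 5 of 25 fell and 1 rose, with the same counts when adjusted over the list alone (adjusted p = 0.0259; adjusted p = 0.178 with an estimated correlation). Desmoplakin, DSP, had a log2 fold change of -0.75 ± 0.093, GRHL2, an epithelial transcription factor, -0.69 ± 0.10, and the tight junction genes TJP1 and OCLN -0.65 ± 0.098 and -0.56 ± 0.13. The desmosomal cadherin DSG3 was the member that rose, by 0.55. The shift of the list was lost without shCtrl 1 (adjusted p = 0.0729), without shSCUBE3 2 (adjusted p = 0.0521) and over genes above background (adjusted p = 0.0595). Between 1 and 3 members fell in the fits without 1 array: DSP passed in all 6, TJP1 in 4, GRHL2 in 3, and OCLN and DSG3 in 0.

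Cell cycle genes shifted downward with few members past the threshold. Of 40 mitosis and G2/M genes 5 fell and 0 rose, or 12 and 0 when adjusted over the list alone (adjusted p = 1.54e-06; adjusted p = 0.147 with an estimated correlation), with a median log2 fold change of -0.24. CKS2, a subunit that binds cyclin-dependent kinases, had -0.79 ± 0.12, DLGAP5, a spindle protein, -0.64 ± 0.094, PRC1, of the central spindle, -0.59 ± 0.11, and KIF23, a kinesin of cytokinesis, -0.47 ± 0.10. Of 38 DNA replication and G1/S genes 5 fell and 0 rose, or 10 and 0 when adjusted over the list alone (adjusted p = 1.72e-05; adjusted p = 0.0583 with an estimated correlation). GINS2 of the replicative helicase had -0.95 ± 0.15, RRM2 of ribonucleotide reductase -0.66 ± 0.11, POLA2 of the primase complex -0.62 ± 0.12 and thymidylate synthase, TYMS, -0.56 ± 0.095. In fits without 1 array between 1 and 2 mitosis genes and between 0 and 2 replication genes fell. DLGAP5 passed in all 6, CKS2 in 5 and GINS2 in 4, POLA2 and TYMS in 1 each, and PRC1, KIF23 and RRM2 in 0.

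**Figure D2:**
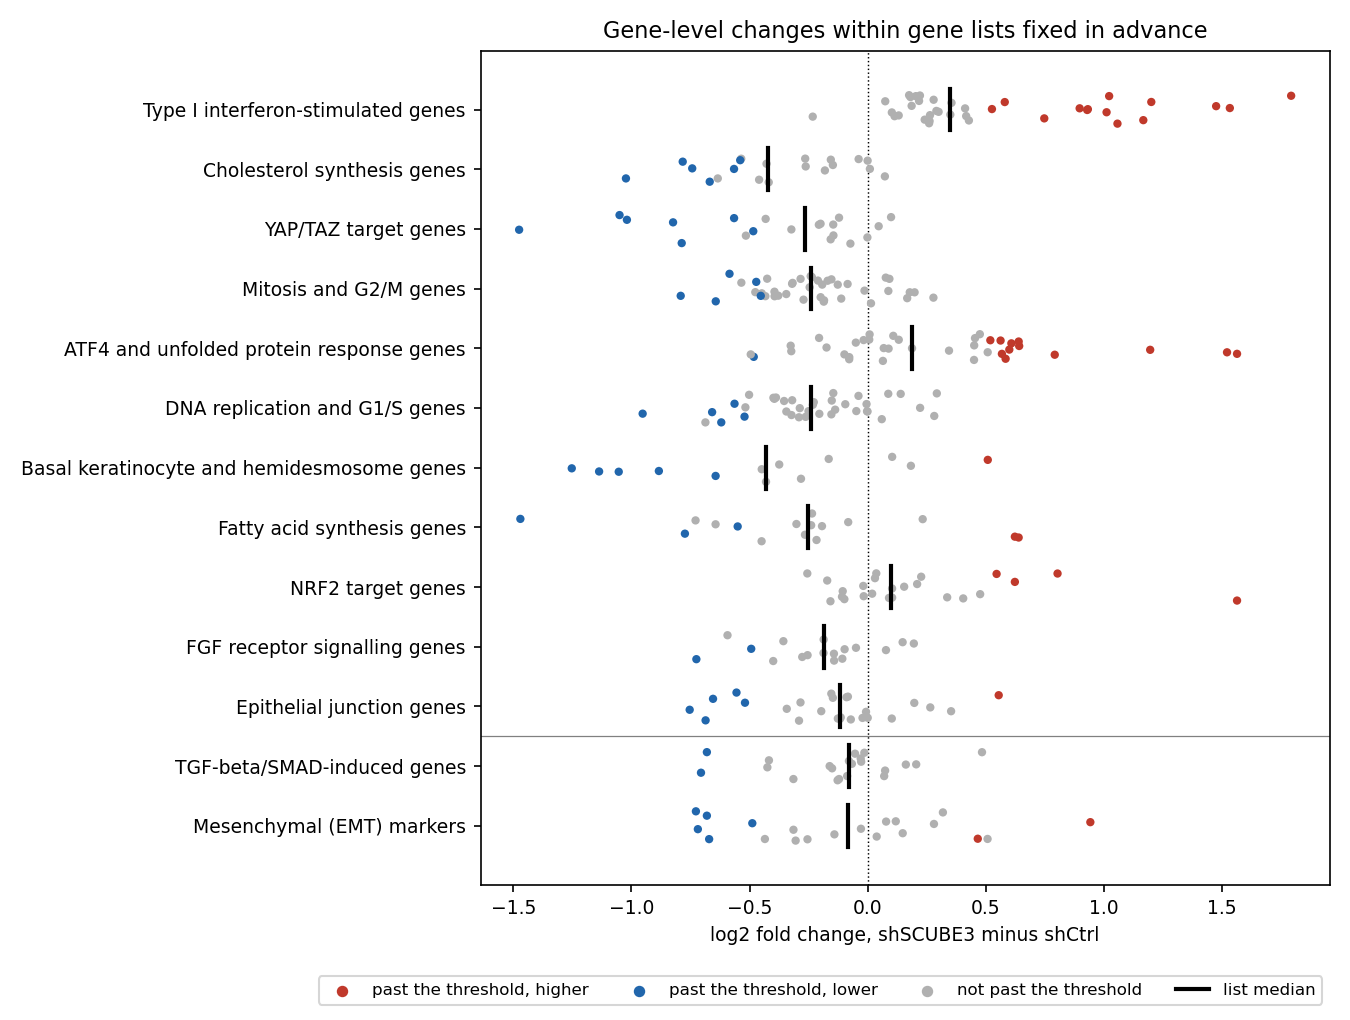
Log2 fold change of each measured member, shSCUBE3 minus shCtrl (horizontal axis), for the 11 lists past the camera test and, below the grey line, 2 that were not, the TGF-beta/SMAD-induced genes and the mesenchymal markers. Points are genes, coloured by whether they passed the threshold, and black bars are list medians; the medians run from 0.35 for the interferon list to -0.43 for the basal keratinocyte list.

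Of 17 FGF receptor signalling genes 2 fell and 0 rose, or 3 and 0 when adjusted over the list alone, and the list shifted downward (adjusted p = 0.016; adjusted p = 0.245 with an estimated correlation). The shift was lost without shCtrl 1 (adjusted p = 0.0572), without the dimmest 30% of genes (adjusted p = 0.172) and over genes above background (adjusted p = 0.174). SPRY1, a feedback inhibitor of receptor tyrosine kinases, had a log2 fold change of -0.49 ± 0.10, and its call was lost in all 6 fits without 1 array. IL17RD, another feedback inhibitor, was at background in both groups and kept its call in 1 of these fits. The ERK and immediate early list did not pass (adjusted p = 0.165): of 26 genes 3 fell and 1 rose, or 4 and 1 when adjusted over the list alone, with 2 lower and 0 higher in each fit without 1 array. Fry passed the ERK list downward (adjusted p = 0.0453). DUSP5, a nuclear ERK phosphatase, had -0.96 ± 0.097 and cyclin D1, CCND1, -0.69 ± 0.092, both in all 6 fits, and MYC rose by 0.50 with the call lost in all 6. Of 13 EGFR ligands and receptors 2 fell and 1 rose, or 2 and 2 when adjusted over the list alone (adjusted p = 0.621). The receptor genes MET and EGFR had -0.59 ± 0.093 and -0.55, and the ligand gene EREG rose by 0.77 ± 0.15. MET, EGFR and EREG lost their calls in all 6 fits without 1 array.

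TGF-beta/SMAD-induced genes did not pass as a list (adjusted p = 0.141), with 2 of 21 lower and 0 higher, the same when adjusted over the list alone. The alternative test fry passed the TGF-beta list downward (adjusted p = 0.0283). SMURF2, a ubiquitin ligase of the pathway, had a log2 fold change of -0.71 ± 0.096 in all 6 fits without 1 array, and the growth factor gene PDGFB had -0.68 ± 0.12 with the call kept only without shSCUBE3 2. Of 17 BMP-responsive genes ID3 alone passed, rising by 0.50 ± 0.11, with a call lost in all 6 fits without 1 array (list adjusted p = 0.523). The BMP list had 1 riser and 1 faller when adjusted over the list alone. Among its members above background the largest difference was in NOG (-0.59 ± 0.16, adjusted p = 0.0756). NOG passed with an intensity trend and robust prior (adjusted p = 0.028) and without the dimmest 30% of genes (adjusted p = 0.0283). It also passed over genes above background (adjusted p = 0.0304) and without shCtrl 2 (adjusted p = 0.0446). Hedgehog genes did not pass as a list (adjusted p = 0.165). Of 12 members 0 were past the threshold with limma, 0 when adjusted over the list alone and 0 by the methods' t-test. At an unadjusted p under 0.05 there were 2. The Hedgehog list joins targets with pathway components and co-receptors, so its direction does not measure target levels alone. Fry passed the Hedgehog list downward (adjusted p = 0.0472). Among members above background the largest difference was in PTCH1, the Hedgehog receptor (-0.47 ± 0.13, adjusted p = 0.0933), which passed without the dimmest 30% of genes (adjusted p = 0.0381) and over genes above background (adjusted p = 0.041). CDON, a co-receptor at background in both groups, from which no fold is read, passed without shSCUBE3 2 (adjusted p = 0.0427) and with an intensity trend and robust prior (adjusted p = 0.0331).

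Mesenchymal markers went both ways, and the list did not pass (adjusted p = 0.271): of 20 genes 5 fell and 2 rose, or 6 and 3 when adjusted over the list alone, with 1 to 3 lower and 1 higher in the fits without 1 array. Fry passed the mesenchymal list downward (adjusted p = 0.0217). SNAI2, the transcription factor Slug, rose by 0.94 ± 0.11 (SE, adjusted p = 0.00512) in all 6 fits without 1 array, and ITGA5, a fibronectin receptor subunit, rose by 0.47 with the call lost in all 6. Vimentin, VIM, had a log2 fold change of -0.68, past the threshold in 3 of these fits, and fibronectin, FN1, -0.72, past it in 6. The cadherin gene CDH11 was not above background in shSCUBE3 and was at least 1.35-fold lower there, with the call lost in all 6 fits. Of 24 metalloproteinases and invasion proteases 3 fell and 1 rose, the same when adjusted over the list alone, with 1 lower and 0 higher in each fit without 1 array (list adjusted p = 0.106). ADAMTS1 had -1.09 ± 0.14, past the threshold in all 6 fits, and the lysosomal protease CTSB -0.56 ± 0.093, past it in 0, and the sheddase ADAM17 rose by 0.50, also past it in 0. Of 35 squamous differentiation genes 3 rose and 1 fell, or 5 and 1 when adjusted over the list alone, with 0 to 2 higher and 0 to 1 lower in the fits without 1 array (list adjusted p = 0.0689). CSTA, cystatin A of the cornified envelope, rose by 0.63 ± 0.10 and KLF4 by 0.57, whereas periplakin, PPL, had -0.73 ± 0.12. CSTA kept its call in 1 of the 6 fits, KLF4 in 0 and PPL in 3. The squamous list passed without shCtrl 2 (adjusted p = 0.0473) and without shCtrl 3 (adjusted p = 0.0438), and the protease list without shSCUBE3 1 (adjusted p = 0.0495).

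In the NF-kB and cytokine list 2 of 29 genes rose and 3 fell, or 4 and 4 when adjusted over the list alone. The list did not pass (adjusted p = 0.165), and the fits without 1 array gave 1 to 2 risers and 1 faller. Fry did not pass it either (adjusted p = 0.0726). Its median was 0.13, with 18 genes higher and 11 lower, and 0.21% of 10000 random lists matched on mean level had a median as high. Random lists do not carry the correlation within the list, estimated at 0.056. CCL20 and the neutrophil chemokine CXCL8 rose, CXCL8 by 0.62 with the call kept in 5 of the 6 fits without 1 array, and IL1B had a log2 fold change of -0.65 ± 0.096 in all 6. Of 25 apoptosis regulators 2 rose and 0 fell, the same when adjusted over the list alone (list adjusted p = 0.106). XIAP, a caspase inhibitor, rose by 1.09 ± 0.20, and the initiator caspase CASP8 by 0.72 ± 0.13. XIAP kept its call in 2 of the 6 fits and CASP8 in 0. Of 25 p53 targets PMAIP1, which encodes NOXA, rose by 0.81 ± 0.12 in all 6 fits, and 2 rose when adjusted over the list alone (list adjusted p = 0.124, and 0.0444 without shCtrl 3). Fry passed the p53 list upward (adjusted p = 0.0453).

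Wnt genes, angiogenesis factors and PI3K/AKT/mTOR components did not pass as lists (adjusted p = 0.165, 0.165 and 0.217). Fry passed each of them downward (adjusted p = 0.0379, 0.0123 and 0.0123). The Wnt list joins targets with ligands and other pathway genes, so its direction does not measure target levels alone. Of 24 Wnt genes 3 fell and 0 rose, or 4 and 1 when adjusted over the list alone, with 1 to 3 lower in the fits without 1 array. DKK3 had a log2 fold change of -0.81 ± 0.11 in all 6 fits, and WNT7B -0.71 ± 0.12 with the call kept only without shSCUBE3 1. Of 23 angiogenesis factors 3 fell and 0 rose, the same when adjusted over the list alone, with 1 to 2 lower in the fits without 1 array. The largest change among them was in THBS1, thrombospondin 1, with -1.26 ± 0.10 in all 6 fits. PIK3CB, a catalytic subunit, was the sole gene of 27 in the PI3K list past the threshold, also when adjusted over the list alone, with -0.58 ± 0.10 and the call kept only without shSCUBE3 1. Of 21 Notch genes 0 passed with limma, 0 when adjusted over the list alone, 0 by the methods' t-test and 4 at an unadjusted p under 0.05 (list adjusted p = 0.735), the largest difference being NOTCH2 with -0.39 ± 0.12 (adjusted p = 0.127, and 0.00949 with an intensity trend and robust prior). The Notch list had a median of 0.0046 and a mean of -0.042, so that its sign was not settled.

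Respiratory chain genes did not pass as a list (adjusted p = 0.271): of 34 genes COXFA4 fell and UQCRB, of complex III, rose by 0.64 ± 0.098, the same when adjusted over the list alone. UQCRB kept its call in 3 of the 6 fits without 1 array. Of 29 hypoxia and glycolysis genes 2 fell and 0 rose, or 2 and 1 when adjusted over the list alone (list adjusted p = 0.858). They were the mitophagy receptor BNIP3L with -0.62 ± 0.10 and hexokinase HK1 with -0.59 ± 0.12, which kept their calls in 1 and 0 of the 6 fits. The median of the hypoxia list was 0.033 and its mean -0.0085. Of 38 ribosomal protein genes 0 passed with limma, 0 when adjusted over the list alone, 0 by the methods' t-test and 6 at an unadjusted p under 0.05 (list adjusted p = 0.634). The ribosomal median was -0.035 and turned to 0.0095 after quantile normalization. RPS25, with the largest difference, had -0.38 ± 0.092 (adjusted p = 0.0577, 0.02 without the dimmest 30% of genes, 0.0222 over genes above background and 3.44e-05 with an intensity trend and robust prior). Of 14 housekeeping genes PPIA, cyclophilin A, fell by 0.41 ± 0.095, also when adjusted over the list alone (list adjusted p = 0.165). The housekeeping median was -0.20, 8 of the 14 had an unadjusted p under 0.05, and 9 were lower and 5 higher in shSCUBE3. The list passed with fry (adjusted p = 0.0217), and 0.83% of 10000 random lists matched on mean level had a median as low. The PPIA call was lost after quantile normalization (adjusted p = 0.0642), median centring (adjusted p = 0.0528) and cyclic loess (adjusted p = 0.0518), and in all 6 fits without 1 array.

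Markers of other cell types passed no list test. Leukocyte markers had 0 of 16 past the threshold with limma, 0 when adjusted over the list alone, 0 by the methods' t-test and 3 at an unadjusted p under 0.05 (list adjusted p = 0.165), and 12 of the 16 were higher in shSCUBE3. Fibroblast markers had 0 of 14 by the first 3 of these measures and 1 at an unadjusted p under 0.05 (list adjusted p = 0.271). Endothelial markers had 0 of 12 by all of them (list adjusted p = 0.835). Over all genes 3517 of 17687 had an unadjusted p under 0.05. Among markers above background the largest differences were 0.48 ± 0.17 for CD14 (adjusted p = 0.17), -0.37 ± 0.12 for PDPN (adjusted p = 0.128) and -0.21 ± 0.13 for CDH5 (adjusted p = 0.441). FCER1G, a leukocyte marker above background on 1 array, from which no fold is read, passed with an intensity trend and robust prior (adjusted p = 0.0334).

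The spiked hybridization controls differed between the groups that all gene comparisons rest on. The 14 bio controls averaged 10.32 ± 0.033 in shCtrl and 10.66 ± 0.023 in shSCUBE3 (mean ± SD, n = 3), a difference of 0.34 in log2. All 14 were higher on every shSCUBE3 array than on any shCtrl array (exact permutation p = 0.1, 2-sided, the smallest that 3 against 3 allows). The 4 cre controls differed by 0.12 in the same direction, and the 24 poly-A controls added before labelling by 0.012 (exact permutation p = 1.0).

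**Figure D3:**
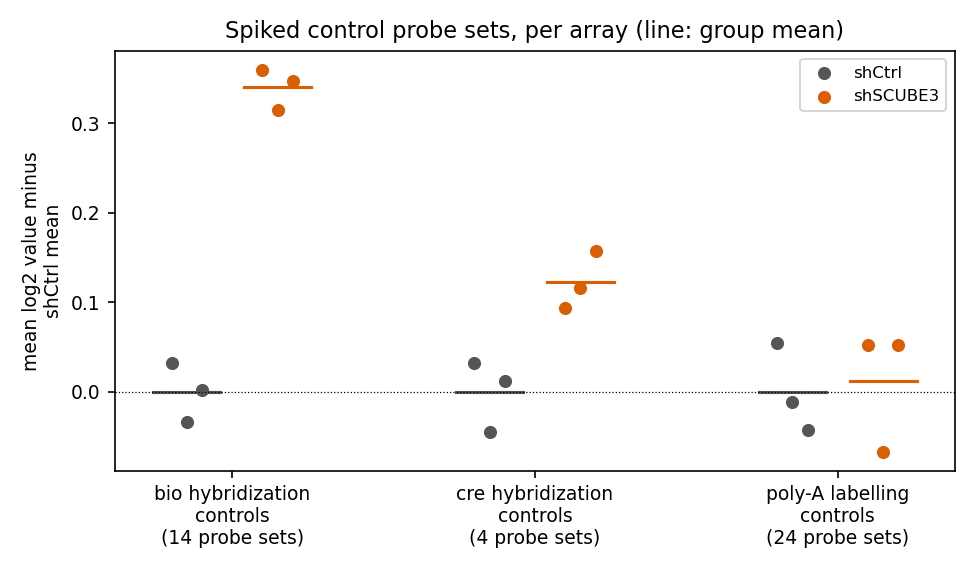
Mean log2 value of 3 classes of spiked control probe sets on each array, relative to the shCtrl mean of the class (vertical axis), for shCtrl and shSCUBE3 arrays; points are arrays and lines are group means. The bio controls are higher by 0.34 and the cre controls by 0.12 on the shSCUBE3 arrays, and the poly-A controls overlap.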

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

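The tests of labelled target, batch labels and cyclic loess in this part were chosen only after the control difference had been seen. Probe sets outside the gene comparison showed differences between the groups. The 14 bio hybridization controls, biotinylated transcripts added just before hybridization, were higher on the shSCUBE3 arrays by a median of 0.36 in log2, and the 4 cre controls by 0.13.

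Less labelled target on the shSCUBE3 arrays may account for this difference, because controls labelled together with the RNA would then stay level, and the poly-A controls differed by a median of 0.016. After cyclic loess 94.7% of the 874 genes were called again. RMA had already normalized the arrays to a common distribution, so little intensity trend may have been left to remove. The result argues only against a trend left in the deposited values as the whole cause of the gene calls. It cannot decide on earlier array effects or on those particular to probe sets. Separate hybridization or scanning batches for the groups cannot be told apart from the hairpins, because the sample table holds 0 batch or date labels. No biological explanation was tested, since these transcripts do not come from the cells.

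Among the 3739 transcript clusters without a gene name in the annotation used here, 80 passed the threshold when all 21448 transcript clusters were tested, 27 higher and 53 lower in shSCUBE3.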

How the results depend on the processing

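The cyclic loess setting and the restriction to genes above background were chosen after the data were seen; the cause of the differences was not tested except where the setting itself gives it. The 874 calls (337 higher, 537 lower) became 39 (14, 25) with the methods' t-test, 1457 of whose genes had an unadjusted p under 0.05 and the fold. They became 1506 (580.0, 926) with an intensity trend and robust prior. With fewer genes tested they became 1336 (507, 829) without the dimmest 30% and 1362 (518, 844) over genes above background. With the fold limit at 2 they became 92 (34, 58). With fewer arrays, leaving out 1 at a time, they ranged from 245 to 415 (86 to 131 higher, 159 to 284 lower). With array weights, mean probe sets, all transcript clusters, quantile normalization, median centring, cyclic loess or no fold limit the counts stayed within 1.5 times. Quantile normalization gave the largest change of the share of higher calls among the scalings, 41.0% against 38.6%.

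With the replicate number as a block the calls became 225 (73, 152). The numbers share no more than a name: deviations of same-numbered arrays correlated between -0.016 and 0.014, and 0 arrays correlated best with their own number. The block changed no call of a gene list.

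Of the 33 lists 11 passed, 1 with an estimated correlation and 20 with fry, and between 9 and 13 in the other settings. Fry passed the 11 lists past camera and also the TGF-beta, Hedgehog, mesenchymal, ERK, Wnt, angiogenesis, PI3K, p53 and housekeeping lists. Directions turned only for results near 0 and past no test (for lists, that of the test; medians are given): SCUBE3 ranged from -0.37 to 0.063 with 1 array left out (0.019 without shCtrl 1, 0.063 without shSCUBE3 2), and SCUBE2 from -0.097 (without shCtrl 2; -0.049 without shSCUBE3 3) to 0.20. It was 0.0095 for ribosomal genes after quantile normalization. With 1 array left out the median ranged from -0.054 to 0.0089 for endothelial markers (highest without shCtrl 1), from -0.014 to 0.031 for hypoxia genes and from -0.057 to 0.016 for Notch genes (-0.014 and -0.013 without shCtrl 3). Fry gave the hypoxia list, median 0.033, a downward direction.

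Of 78 named genes past the threshold, 44 stayed past it in all 6 fits without 1 array, 47 with the block and 7 with the methods' t-test. Signal over background limits the dim genes: 37 of the 874 calls were below background on all arrays and 30 on all arrays of 1 group.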

Other observations

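The 10 gene lists below were chosen after the results were seen, as were the tests of SCUBE3 background, of exchanged arrays and labels, of the hairpin, of leukocytes and of the splits for gene counts. The p-values of these lists come from the same values that were seen before the choice, so they describe the lists and are not independent evidence.

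Of 14 measured cytosolic aminoacyl-tRNA synthetases 6 rose and 0 fell, or 3 to 5 and 0 in the fits without 1 array (camera adjusted p = 7.44e-07 over these 10 lists; adjusted p = 0.0769 with an estimated correlation), among them WARS1 by 0.96 ± 0.13 (SE, n = 3 per group), GARS1 by 0.78 ± 0.11 and YARS1 by 0.77 ± 0.10. Of 24 cytosolic chaperones 4 fell and 0 rose, or 2 to 3 and 0 in the fits without 1 array (adjusted p = 7.44e-07; adjusted p = 0.281 with an estimated correlation), with log2 fold changes of -1.20 ± 0.093 for HSP90AA1 and -0.70 ± 0.10 for HSPH1, past the threshold in 6 and 5 of the fits without 1 array. Of 28 proteasome subunits 2 fell, PSMD2 and PSMD1, past the threshold in 1 and 0 of the 6 fits without 1 array (adjusted p = 0.0281; adjusted p = 0.243 with an estimated correlation). In the tryptophan, kynurenine and aryl hydrocarbon list 4 of 12 rose, KYNU, WARS1 and CYP1B1 in all 6 fits and CYP1A1 in 1 (adjusted p = 0.031; adjusted p = 0.353 with an estimated correlation).

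The other 6 lists did not pass; of the genes named from them, VAMP3 and HLA-F kept their calls in 0 of the 6 fits without 1 array, SAR1B, NCAPH and ERAP2 in 1 and DEGS1 in 2. In the sphingolipid list UGCG, DEGS1, SPTLC2 and B4GALT6, the last at background in both groups, fell among 18 genes (adjusted p = 0.0932), and in the COPII list SEC23A and SAR1B among 14 (adjusted p = 0.211). VTI1B, a SNARE of endosomal fusion, had a log2 fold change of -1.27 ± 0.092, and VAMP3 also fell among 25 SNARE and Golgi genes (adjusted p = 0.437). SMC1A and NCAPH fell among 19 cohesin and condensin genes (adjusted p = 0.437). HLA-F rose and ERAP2 fell among 14 antigen presentation genes (adjusted p = 0.219). Complement factor B, CFB, rose by 1.26 ± 0.10 and CD59 fell among 14 complement and acute phase genes (adjusted p = 0.437).

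SCUBE3 was not lower on the shSCUBE3 arrays beyond its error. A probe set at background may account for this, since it was above background on 0 of the 6 arrays. With 1 array under the wrong group label, moving it should raise the 874 calls. Moving any array instead left 0 calls with limma, 0 with the methods' t-test and 1491 to 1881 genes at an unadjusted p under 0.05. With 1 shCtrl and 1 shSCUBE3 array exchanged back the calls were also 0 with both tests. At an unadjusted p under 0.05 there were then 519 to 888 genes, against 3517 with the labels as given. The labels of the groups exchanged as a whole cannot be told apart from the labels as given, because the SCUBE3 difference of -0.11 has a 95% interval reaching 0.43.

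The rise of the type I interferon-stimulated genes is open to more than 1 explanation. An intensity-dependent array effect is argued against by random lists matched on mean level, of which 0% of 10000 had a median as high as 0.35, the highest being 0.16. The samples are an established cell line, and the labels name no source of leukocytes. The markers alone could not exclude leukocytes mixed into the shSCUBE3 cultures. With limma 0 of 16 markers passed the threshold, with 3 at an unadjusted p under 0.05 and 0 by the methods' t-test. Those 3 are no excess, since 3517 of all 17687 genes had such an unadjusted p. Yet 12 of the 16 markers were higher, and FCER1G passed with an intensity trend and robust prior (adjusted p = 0.0334). No fold is read from FCER1G, because it was above background on 1 array. The 5 most abundant markers were CD68 (mean level 7.23), ITGAX (6.96), NKG7 (6.52), CSF1R (6.46) and TYROBP (6.41). Their mean difference had an upper 95% bound of 0.21. This bound comes from the spread between the 5 genes and leaves out the spread between arrays, so it does not limit the difference between the groups. Each of the 5 also lies above the median gene (5.63), where a small share would be hidden. A response to this hairpin or vector independent of SCUBE3 cannot be told apart from an effect of lower SCUBE3, itself untested, because 1 hairpin group was analysed here.

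The 6 arrays can be split in 10.0 ways into 3 and 3, too few for a share under 0.05. The real split gave 874 genes, 337 higher and 537 lower, where the highest of the other splits gave 0, 0 and 0 with limma, and 11 gene lists where the highest other gave 5. In each case 1 split, the real one, reached the real value.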
